A study of Mus musculus with 3 samples.

How the data were processed

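Gene expression was measured in 3T3-L1 cells, an established mouse preadipocyte line that turns into fat-storing adipocytes after hormonal induction, at 2, 8 and 20 days after induction. There were 3 arrays, 1 per day, so the series holds no replicates, no difference between days could be tested, and no p-value is given. Per the labels' protocols, total RNA was extracted with Trizol, and cyanine-3 labelled cRNA was made with an Agilent kit for 1-colour arrays. The arrays shared 1 slide and were scanned together, per the file headers, so no slide or scan separates the days.

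Each array's deposited intensity values are linear brightness readings of spots, read out with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. The processed intensity is background-corrected by that software, per the file headers, and is not scaled between arrays. Other deposited columns, used as yes or no marks, say whether a spot was well above background, saturated or an outlier, per the file headers. The deposited log2 values of the series table equal log2 of the processed intensity plus 1 constant per array, to within 0.01 for 100% of probes. Those constants were -9.37, -9.31 and -9.86 for days 2, 8 and 20, and the column medians were -4.80, -4.69 and -4.89. Scale, centring and direction of the series table are thereby known, and its columns were used as an alternative source of values.

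The main values were log2 of the processed intensity minus each array's 75th percentile over non-control probes. Control spots and outlier spots were left out, spots of the same probe were averaged, and saturated spots would have been kept, but 0 were saturated on each array. The files carry no gene names. Of 39429 non-control probes, 26579 were named by matching their RefSeq accession, without its version, to a gene table of assembly GRCm38.p6, and 12850 stayed unnamed. The file headers name an earlier mouse build for the array design, so no coordinates are given. The named probes covered 20142 genes, 5370 of them with more than 1 probe. A gene took the value of its brightest probe, by the mean over the 3 arrays. For 38 genes, another probe was well above background on an array where the used probe was not.

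A difference was measured where the used probe was well above background on both arrays, and genes with an absolute log2 difference of 1 or more (2-fold) or 2 or more (4-fold) were counted. Where only 1 of the 2 arrays had the gene well above background, a bound was computed: the bright value minus the higher of the dim value and the lowest signal among probes well above background on the dim array. Such genes are described as at least N-fold higher or lower and were counted apart. Where the dim value lay above that lowest signal, as for Ifna1 on day 20 (-5.31 against -5.91), the bound is the plain difference. Small bounds are therefore not strict minimums. The levels of different probes were not set against each other as amounts of transcript, and served only to order or group probes by brightness.

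The error beside a gene is a technical SD. It was taken from probes printed 10 times on each array (244, 244 and 245 of them on days 2, 8 and 20), as a function of signal, and holds the spread between spots of an array, not the spread between cultures or labelling reactions. Its median was 0.076 from day 2 to day 8, 0.0805 from day 8 to day 20 and 0.0761 from day 2 to day 20. With 1 array per day the spread between cultures could not be estimated. From this spread alone, fewer than 1 gene per comparison was simulated to pass 2-fold (0.12, 0.07 and 0.01 genes on average over 100 simulations).

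Before the data were examined, 36 gene lists were fixed, covering stages of adipocyte differentiation, lipid and glucose metabolism, secreted products, stress responses, handling of the cells, control genes and markers of other cell types. A list's median over its measured members is given relative to the median of all measured genes. It was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these arrays only. A list stood apart with a percentile under 2 or over 98, which about 4% of lists of independently drawn genes would do. Lists whose members vary together between arrays could pass more often. Lists with fewer than 5 measured members have no median. Error bars of list medians are bootstrap SDs over members from 1000 resamples. Lists overlap: 12 of the 20 adipocyte identity genes are also in another list.

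The rule for the genes named was fixed at the same time: 10 anchor genes in every comparison, the 6 genes with the largest differences and the 4 with the largest bounds in each direction, up to 4 members in the direction of a list that stood apart and 2 against it, up to 3 members at least 2-fold apart of every other list, and 5 genes for each time course pattern. Clone names were left out of the largest differences. Genes outside this rule are said to have been chosen after their values were seen.

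Alternatives fixed in advance were normexp background correction with an offset of 50, quantile normalization, scaling on the median of probes well above background, scaling on the spike-in probes, cyclic loess between arrays, the series table, the mean of a gene's probes, its dimmest probe well above background, and 3 other filters on dim probes. Normexp was planned on mean spot signals, which the files do not hold, so median spot signals with the median local background were used.

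The procedure was tested on simulated arrays with 200 genes changed by known amounts. In the simulation of day 2 to day 8, which ran on 12504 genes, 67 of 67 genes set at 3-fold, 66 of 66 set at 6-fold and 0 of 67 set at 1.5-fold were counted as at least 2-fold apart. For day 8 to day 20 (12839 genes) these were 67 of 67, 66 of 66 and 1 of 67, and for day 2 to day 20 (12503 genes) 67 of 67, 66 of 66 and 0 of 67. None of the unchanged genes was counted (0 of 12304, 0 of 12639 and 0 of 12303). Both simulated arrays started from the same day's values, with noise from the spread between spots alone. These counts therefore test the calculation and give no error rate for spread between cultures or labelling reactions. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.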

Results

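Transcript levels in 3T3-L1 adipocytes were compared between day 2, just after induction of differentiation, day 8 and day 20. The study set out to measure how adipocyte hypertrophy, the enlargement of fat cells as they fill with lipid, is accompanied by changes in gene expression. Each day was represented by 1 Agilent 1-colour array of total RNA. With no replicates, every difference below compares 2 arrays, and the error given beside it is technical. Each array held 44397 spots, of which 43020 were not controls. Spots well above background made up 55.9% on day 2, 56.9% on day 8 and 55.3% on day 20, and genes well above background numbered 12489, 12836 and 12574. The 75th percentile of processed intensity was 736, 697 and 1029, against a median local background of 19, 18.5 and 18.5. In all, 13456 genes were well above background on at least 1 array and 11810 on all 3.

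From day 2 to day 8, genes of the mature adipocyte were higher and genes of the cell cycle were lower. Adipoq, which encodes the adipocyte hormone adiponectin, was 14.2-fold higher on day 8 (log2 difference 3.83, technical SD 0.066), and Slc2a4, the insulin-responsive glucose transporter, was higher by 3.42 (SD 0.072). Pparg, the nuclear receptor that drives adipocyte differentiation, was 3.27-fold higher (1.71, SD 0.068). Cebpb, a transcription factor of the first phase of differentiation, was 2.26-fold lower (-1.18, SD 0.065). Genes of the interferon response were higher by a list median of 3.26 relative to all genes, and cell cycle genes were at -4.12.

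Among 12044 genes measured on both days, 1665 were at least 2-fold higher on day 8 and 1557 at least 2-fold lower, and 622 and 384 passed 4-fold. Another 304 genes were at least 2-fold higher and 134 at least 2-fold lower as bounds, with 1 of the 2 days not well above background. Of the 768 genes that passed 2-fold and had another measured probe, 738 (96.1%) had their other probes on the same side. The median of all measured genes was -0.06. Of the 34 lists with a median, 18 stood apart as higher and 2 as lower.

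The other anchor genes measured on days 2 and 8 were under 2-fold. Fabp4, the fatty acid carrier of adipocytes, was at -0.05 (SD 0.066), a value that turned to 0.16 with cyclic loess. Cebpa, a late-phase transcription factor, was at -0.40 and Dlk1, the preadipocyte inhibitor of differentiation, at -0.46, with its other probe at -0.52. Fasn, fatty acid synthase, was at 0.39 and Plin1, the main coat protein of adipocyte lipid droplets, at 0.80. Lep, encoding leptin, was not well above background on day 2 and at least 1.16-fold higher on day 8.

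**Figure D1:**
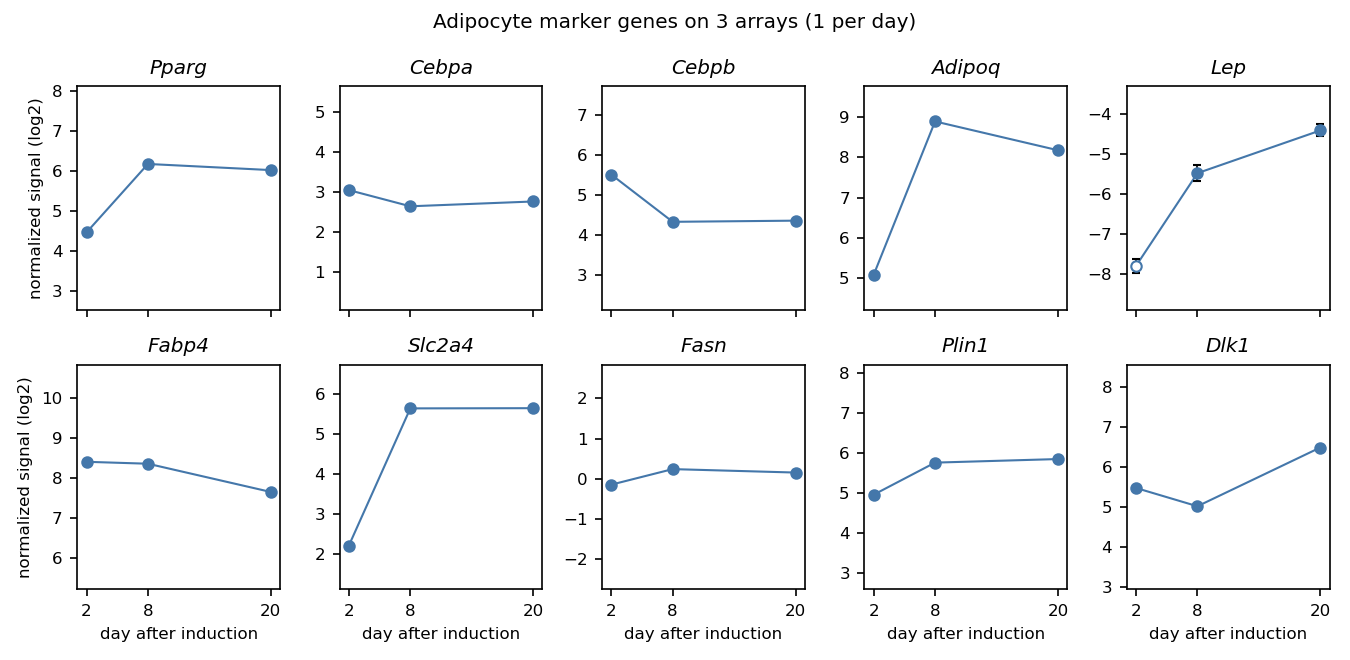
Normalized log2 signal of the 10 anchor genes against the day after induction (2, 8 and 20), 1 array per day, with every panel spanning the same number of log2 units. Bars are technical SDs, mostly smaller than the points, and the open point marks Lep on day 2, not well above background. Adipoq and Slc2a4 were higher on day 8 than on day 2 by 3.83 and 3.42, while from day 8 to day 20 Dlk1 was higher by 1.47 and Slc2a4 differed by 0.01.

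The largest measured difference was that of Ghrh, encoding growth hormone-releasing hormone, which was higher on day 8 by 11.11 (SD 0.188). Adrb3, the adrenergic receptor typical of adipocytes, followed at 10.08 (SD 0.188), then Selenbp1, a selenium-binding protein, at 9.20, Itih4, a plasma protein, at 8.17, Slc36a2, an amino acid transporter, at 8.16, and Cox7a1, a cytochrome oxidase subunit of muscle and brown fat, at 7.62. The day 2 signals of Ghrh, Adrb3, Itih4 and Slc36a2 lay near the lowest well above background, so the size of these differences rests on dim spots. The largest bounds were those of Cox8b, another cytochrome oxidase subunit (at least 1689-fold higher), Plppr3 (at least 273-fold), Ifit3, an interferon-induced gene (at least 251-fold), and Sucnr1, the succinate receptor (at least 245-fold).

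In the other direction, Retnla, encoding a resistin-like secreted protein, was at -9.77 (SD 0.199). The next 5 all belong to a family of eosinophil-associated ribonucleases: Ear6 (-8.38), Ear10 (-8.20), Rnase2a (-8.11), Ear1 (-7.94) and Ear2 (-7.65). Members of this family are close to identical in sequence, so which of them was transcribed is uncertain. Of 12 eosinophil markers examined beside them, 3 were well above background on day 2, and 0 were at least 2-fold lower on day 8. Pip, a secreted protein, was at least 296-fold lower, Ang4, also a ribonuclease, at least 89.4-fold, Lgals7, a galectin, at least 80.6-fold, and Kiss1, a neuropeptide precursor, at least 60.0-fold.

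Of 13 late adipogenic regulators, 6 were at least 2-fold higher and 1 lower, with a relative median of 0.96 (percentile 99.9). Klf15, a Krüppel-like factor of mature adipocytes, was at 4.63, Ebf2 at 1.18 and Srebf1, the regulator of lipogenic genes, at 1.17, against Tle3 at -2.16 and Rxra at -0.86. Of 14 early regulators, 3 were higher and 4 lower (relative median -0.06, percentile 44.4), among them Klf5 at -4.20, Egr2 at -2.92 and Zfp467 at 2.60. Adipocyte identity genes had a relative median of 1.16, with 10 of 18 higher and 0 lower. Cfd, the serine protease adipsin, was at 6.46, Pck1, the key enzyme of glyceroneogenesis, at 3.99 and Aqp7, the glycerol channel, at 3.86, while Acsl1, an acyl-CoA synthetase, was at -0.77 and Fabp5 at -0.70. Preadipocyte and fibroblast genes did not stand apart (relative median 0.22, percentile 82.0), with Lum at 2.71, Pdgfrb at 2.53 and S100a4 at -2.07.

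Lipid metabolism lists were higher. In lipolysis, 10 of 16 genes were at least 2-fold higher and 1 lower (relative median 1.43), led after Adrb3 by Pnpla3, a lipid droplet enzyme, at 6.06, Hcar1, the lactate receptor, at 4.25 and Pde3b, the phosphodiesterase through which insulin restrains lipolysis, at 3.94. Abhd5, the coactivator of the triglyceride lipase, was at -1.01 and Faf2 at -0.55. In fatty acid and triglyceride synthesis, 11 of 23 were higher and 2 lower (relative median 0.90), with Thrsp at 5.48, Acss2 at 4.16, Acacb at 2.69 and Gpd1 at 2.56, against the elongase Elovl6 at -1.34 and Agpat2 at -1.01. Lipid droplet genes had 9 of 19 higher and 1 lower (relative median 0.94), with Cidea at 5.69, Cideb at 3.22, the seipin gene Bscl2 at 3.13 and Cav1 at 1.92. Fitm2, which acts in droplet formation, was at -1.68 and the droplet coat gene Plin2 at -0.86.

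Branched-chain amino acid catabolism had 12 of 18 genes higher and 0 lower (relative median 1.29), including Bckdha at 2.74, Aldh6a1 at 2.11, Mccc1 at 2.07 and Pccb at 2.05, with Dld at -0.59. Cholesterol synthesis had 11 of 22 higher and 2 lower (relative median 1.1), with the squalene synthase gene Fdft1 at 2.70, Sc5d at 2.00, Mvd at 1.61 and Fdps at 1.45, while Cyp51 was at -1.29 and Hmgcs1 at -1.07. The remaining energy lists did not stand apart. Respiratory chain genes had 1 of 38 higher, Sdha at 1.04 (relative median 0.14, percentile 97.0). Fatty acid oxidation genes had 3 of 22 higher, among them Acot2 at 1.29 and Acaa2 at 1.20 (0.30, percentile 96.1, past the threshold in 1 of 11 alternative settings). In insulin signalling and glucose uptake, 6 of 23 were higher and 3 lower (0.33, percentile 95.0), with the adaptor Grb14 at 2.68 and the small GTPase Rhoq at 2.49.

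Cell cycle genes were lower in 29 of 31 cases and higher in 0 (relative median -4.12, percentile 0). Rrm2, a subunit of ribonucleotide reductase, was at -5.66, and the mitotic genes Aurka, Ccnb1 and Bub1 were at -5.33, -5.23 and -5.23. Glucocorticoid and cAMP targets, which respond to components of common induction cocktails, had 6 of 19 lower and 2 higher (-0.49, percentile 1.74). Lcn2, encoding the lipid carrier lipocalin, was at -6.42, Fkbp5 at -3.54, Pde4b at -2.92 and Sgk1 at -2.33, against Sult1a1 at 6.54 and Errfi1 at 1.12. This list no longer stood apart in 5 of 11 alternative settings.

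Of 24 measured interferon response genes, 19 were at least 2-fold higher on day 8 and 0 lower, and another 7 were at least 2-fold higher as bounds. The guanylate-binding protein genes Gbp3 and Gbp2 were at 7.55 and 6.96, the immunity-related GTPase gene Igtp at 6.50 and Oas1a at 5.37. Chemokines and inflammatory mediators had 13 of 23 higher and 3 lower (relative median 1.28, but 0.39 without a filter on dim probes and 2.33 in genes above the lower quartile of signal), with Ccl9 at 4.57, Ccl2 at 4.25, the haptoglobin gene Hp at 3.80 and Orm1 at 3.37, against Lcn2 at -6.42 and Il6 at -1.70. Beside these lists, macrophage markers had 5 measured members with a relative median of 0.18 (percentile 62.2), of which Cd14 was at 2.96 and the other 4 were under 2-fold.

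Further stress lists stood apart as higher. Hypoxia targets had 16 of 23 higher and 1 lower (1.75), with Ankrd37 at 4.50, Ndrg1 at 4.43, Pdk1 at 3.68 and Egln3 at 3.58. Pfkfb3, a glycolytic regulator, was at -2.12 and Hif1a itself at -0.61. Antioxidant and detoxification genes had 10 of 26 higher and 2 lower (0.74), with the glutathione transferase genes Gstt1, Gstm1 and Gsta4 at 7.09, 4.98 and 3.55 and the epoxide hydrolase Ephx1 at 4.74, against Nqo1 at -1.50 and Prdx1 at -1.30. In the list of p53 targets and senescence, 10 of 26 were higher and 3 lower (0.67), with Glb1 at 3.33, Fas at 3.07, Cdkn2b at 2.17 and Btg2 at 1.82, against Lmnb1 at -2.52, a place lost in 1 of 11 alternative settings. Lysosome and autophagy genes had 13 of 33 higher and 0 lower (0.65), with Lipa at 1.83, Ctsa at 1.56 and Hexa at 1.40. Circadian clock genes had 7 of 14 higher and 1 lower (1.02), with Dbp at 4.74, Bhlhe40 at 2.37 and Per3 at 2.31, while Clock was at -1.39 and Cry1 at -0.68.

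Unfolded protein response genes, of which 8 of 27 were lower and 0 higher, lay at -0.40 (percentile 2.23) and missed the threshold, with Ppp1r15a at -1.64, Asns at -1.50 and Atf4 at -1.43. Immediate early genes had 5 of 19 higher and 4 lower (-0.28, percentile 5.54), among them Ier3 at 3.69 and Jund at 2.33, and heat shock genes 2 of 15 higher and 1 lower (-0.13, percentile 33.6), with the small heat shock protein Cryab at 4.44, Hspa1a at 1.83 and Hspd1 at -1.04. The control lists lay near all genes: ribosomal protein genes at -0.15 with 0 of 37 past 2-fold, and housekeeping genes at 0.03 with 3 of 19 higher and 2 lower, with B2m at 2.34, Pgk1 at 1.84 and Ywhaz at -1.64 as the largest. The own medians of both control lists turned slightly positive with cyclic loess, to 0.002 and 0.17, and that of housekeeping genes also with quantile normalization and spike-in scaling.

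Secreted and structural lists were higher by smaller medians. Adipokines had 6 of 15 higher and 2 lower (0.62), with Igf1 at 4.17 and the chemerin gene Rarres2 at 3.95 beside Cfd and Adipoq, against Sfrp5 at -3.15. Extracellular matrix genes had 7 of 27 higher and 3 lower (0.45), with Thbs1 at 4.59, Spp1 at 3.40, Thbs2 at 2.71 and Fbn1 at 2.54, against Postn at -1.99 and Loxl1 at -1.18. Actin and contractile genes had 6 of 21 higher and 1 lower (0.45), with Myl9 at 6.03, Acta2 at 5.65, Cnn2 at 3.03 and Tagln at 2.48, against Tpm2 at -1.77. The place was lost in 2 of 11 alternative settings for adipokines, 1 of 11 for extracellular matrix and 3 of 11 for actin genes. Matrix proteases and their inhibitors did not stand apart, with 6 of 16 higher and 4 lower (0.03), among them Timp3 at 3.43 and Mmp23 at 2.98.

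Markers of other cell types gave a mixed picture. Brown and beige adipocyte genes stood apart at 0.80 (percentile 98.4, bootstrap SD 1.32) with 3 of 8 measured members higher, Cox7a1, Cidea at 5.69 and Zic1 at 1.07. They did not stand apart in 3 of 11 alternative settings. Of the list's 16 members, 4 were not well above background on either day. As bounds, 1 was at least 2-fold higher on day 8 and 2 were at least 2-fold lower. Muscle markers had 3 of 6 higher (0.68, percentile 97.0), namely Acta1 at 3.64, Des at 3.52 and Tnnt2 at 1.08. Bone and cartilage markers had 3 of 7 higher and 3 lower (0.59, percentile 88.9), with Ogn at 5.14, Comp at 3.68 and Spp1. Of 4 measured endothelial markers, 1 was higher, Egfl7 at 1.63, and of 3 epithelial markers, the keratin genes Krt18 and Krt14 were at 5.62 and -3.53.

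**Figure D2:**
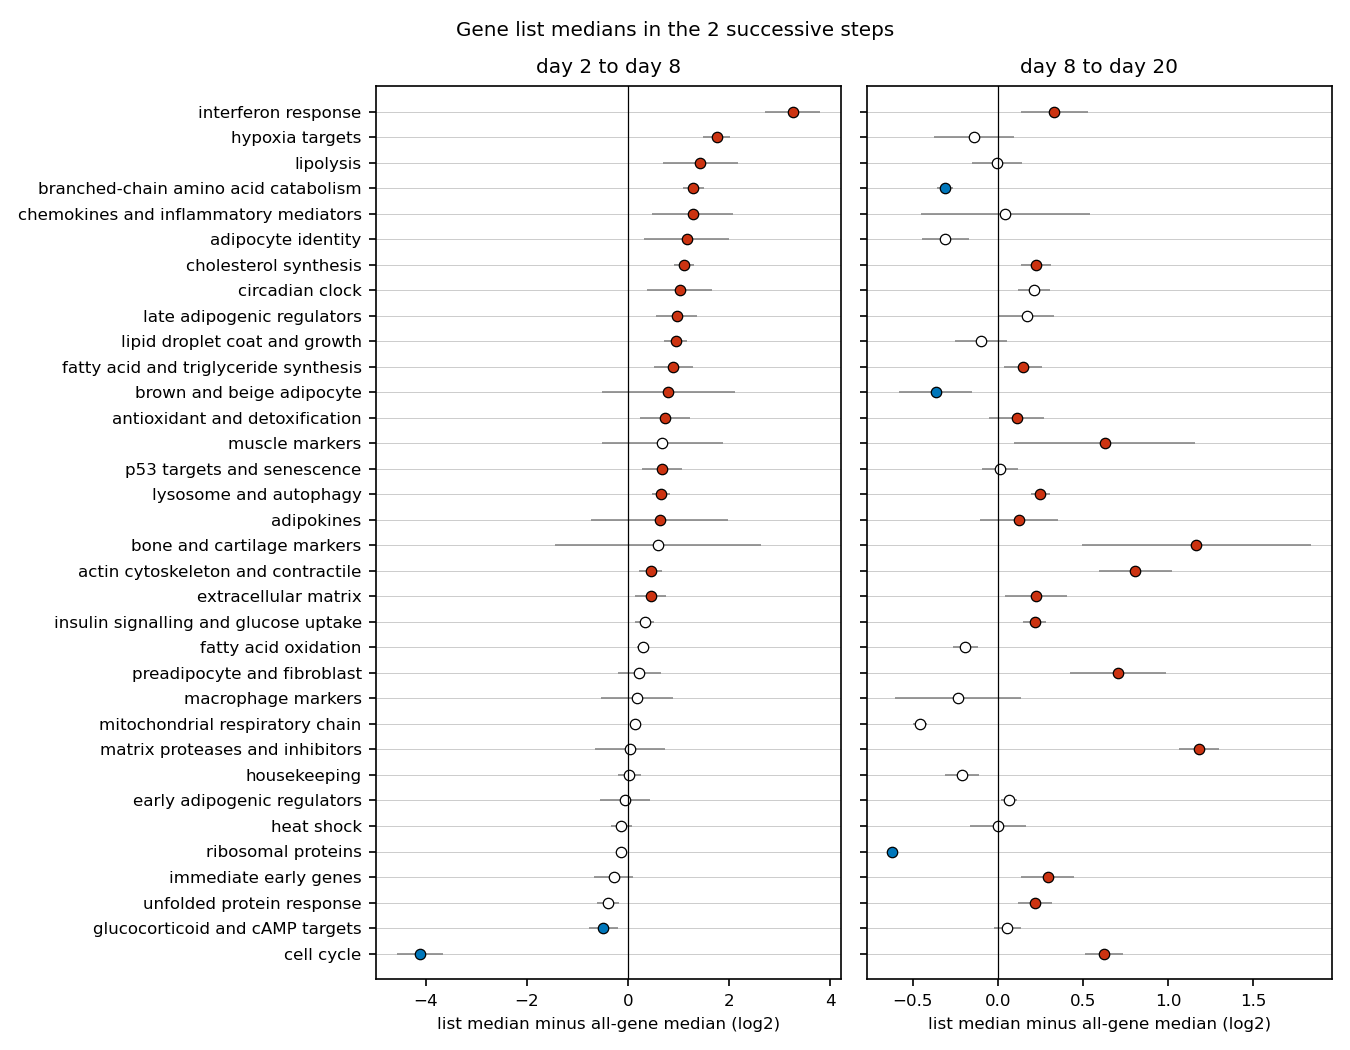
Median of each gene list minus the median of all measured genes (log2) for day 2 to day 8 (left) and day 8 to day 20 (right), 1 array per day, on x axes of different scale. Points are list medians, red where the list stood apart as higher, blue as lower and white where it did not, and bars are bootstrap SDs over members, so that interferon response (3.26) and cell cycle (-4.12) mark the ends on the left and matrix proteases (1.18) and ribosomal proteins (-0.62) on the right.

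From day 8 to day 20 differences were smaller, and the lists with the highest medians were matrix proteases, bone and cartilage markers, contractile genes and preadipocyte genes. Timp3, an inhibitor of matrix metalloproteases, was 9.34-fold higher on day 20 (3.22), Acta2, smooth muscle actin, was higher by 1.81, and Dlk1 was 2.76-fold higher (1.47, SD 0.074), with its other probe at 1.67. Adipoq was 1.65-fold lower (-0.72, SD 0.074) and Fabp4 1.63-fold lower (-0.70, SD 0.074), values that shrank to -0.22 and -0.14 with cyclic loess and to -0.05 and -0.04 with spike-in scaling. Slc2a4 (0.01), Plin1 (0.09), Cebpb (0.03), Cebpa (0.12) and Fasn (-0.09) lay within 2 technical SDs of 0, but between 0.58 (Fasn) and 0.79 (Cebpa) with spike-in scaling. Pparg was at -0.15, and at 0.27 with quantile normalization, 0.20 with cyclic loess and 0.51 with spike-in scaling. Lep was higher by 1.07 (SD 0.244), but its signal was dim and the difference was -0.04 with normexp background correction.

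Among 12321 genes measured on both days, 441 were at least 2-fold higher on day 20 and 214 lower, and 69 and 17 passed 4-fold. Bounds added 63 higher and 65 lower. Of 102 genes past 2-fold with another measured probe, 95 (93.1%) had their other probes on the same side. This split depended on the scaling: 67.3% of the genes past 2-fold were higher in the main values, 83.0% after cyclic loess (620 higher, 127 lower) and 99.0% when the arrays were scaled on the spike-in probes (2098 higher, 21 lower). Without a filter on dim probes the majority turned to the lower side, with 694 higher and 1315 lower (34.5% higher). With normexp the share was kept but the counts fell, to 206 higher and 100 lower, with bounds for 0 and 5. Spike-in scaling moved the median of all genes from -0.05 to 0.62, so the values given here are relative to the bulk of genes on each array. Of the 141 genes the naming rule selected here, 28 changed sign under spike-in scaling, 0 of them past 2-fold. The shift is the same for every gene and smaller than 2-fold, so no gene past 2-fold could have changed sign. Of the 34 lists with a median, 16 stood apart as higher and 3 as lower.

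The 6 largest differences on the higher side were those of Inhbb, encoding a subunit of activin and inhibin (3.89, SD 0.19), Serping1, the inhibitor of the first complement component (3.83, SD 0.203, other probe 3.78), Slco2b1, an organic anion transporter (3.69), Fmod, the collagen-binding proteoglycan fibromodulin (3.62), Aebp1, a secreted matrix protein (3.43), and Ccl17, a chemokine (3.37). On the lower side were Rnase2a (-3.99) and Ear1 (-3.80) of the ribonuclease family, Treml1, a platelet receptor (-3.73), Slc22a20, an organic anion transporter (-2.60), Msln, the mesothelial surface protein mesothelin (-2.47), and Ctnna2, a catenin (-2.43). The largest bounds were those of Edil3 (at least 6.86-fold higher), P2ry6 (at least 6.84-fold), Olfr701 (at least 6.56-fold) and Nat8f6 (at least 6.22-fold), and of Mettl23 (at least 202-fold lower), Ear2 (at least 47.6-fold), Krt15 (at least 5.08-fold) and Vmn2r111 (at least 4.78-fold). The value of Mettl23 rests on 1 spot per array.

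Matrix proteases and inhibitors had 13 of 19 members at least 2-fold higher and 0 lower (relative median 1.18, percentile 100), with Timp1 at 2.26, the collagenase Mmp13 at 2.19 and Plat, tissue plasminogen activator, at 1.90 after Timp3, while Mmp23 was at -0.48. Extracellular matrix genes had 7 of 28 higher and 0 lower (0.22), with Spp1, osteopontin, at 2.36, Thbs1 at 2.21, Fbn1 at 1.97 and the crosslinking enzyme Lox at 1.65, against Col5a3 at -0.77 and Loxl2 at -0.71. Actin and contractile genes had 8 of 22 higher and 0 lower (0.81), with Actg2 at 2.94, Ccn2, connective tissue growth factor, at 2.78 and Myl9 at 2.15, while Actg1 was at -0.48 (0.01 with cyclic loess). Preadipocyte and fibroblast genes had 4 of 17 higher and 1 lower (0.71), with the stromal surface markers Ly6a at 2.58 and Thy1 at 1.81 and the Wnt ligand Wnt5a at 1.15, against Cd34 at -1.17. Alongside these, bone and cartilage markers had 5 of 9 higher and 1 lower (1.17), including Ogn at 1.78, Bglap2 at 1.70 and Sox9 at 1.47, with Col10a1 at -1.56. Muscle markers had 2 of 7 higher (0.63, percentile 98.7), Tnnt2 at 1.44 and Tnni1 at 1.37, but lost their place in 5 of 10 alternative settings. Without a filter on dim probes the medians of the bone and muscle lists were 0.02 and -0.01.

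Cell cycle genes were higher by a relative median of 0.62, with 4 of 31 past 2-fold: Ccnd1, cyclin D1, at 1.94, Ccna2 at 1.29, the proliferation marker Mki67 at 1.05 and Top2a at 1.03, while Cdc6 was at -0.49. Interferon response genes had 7 of 31 higher and 0 lower (0.33), with Ifi27l2a at 2.17, the immunoproteasome genes Psmb8 and Psmb9 at 2.13 and 2.08 and Rsad2 at 1.82. Chemokines and inflammatory mediators did not stand apart (0.04, percentile 69.8), with 9 of 26 higher and 4 lower, among them Cxcl10 at 2.01, Tlr2 at 1.73 and Cxcl5 at 1.57. Macrophage markers measured beside them had 0 of 6 higher and 1 lower, Itgam at -1.13 (relative median -0.23, percentile 9.85, with an own median that turned positive under spike-in scaling).

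Several metabolic and stress lists stood apart as higher by relative medians of 0.11 to 0.29, with few or no members past 2-fold. Fatty acid and triglyceride synthesis (0.15) and cholesterol synthesis (0.23) had 0 members past 2-fold in either direction, with Acaca, acetyl-CoA carboxylase, at 0.65 as the highest of fatty acid synthesis. Insulin signalling (0.22), which lost its place in 2 of 11 alternative settings, had Grb14 at 1.12 and Snap23 at -1.15. Lysosome and autophagy genes (0.25) had 0 of 34 past 2-fold, with Ctsz at 0.93. Unfolded protein response (0.22) and immediate early genes (0.29) each had 1 higher, Atf3 at 1.14 in both, and the immediate early list no longer stood apart in 5 of 11 alternative settings. Antioxidant genes (0.11) had 3 of 26 higher, the heme oxygenase gene Hmox1 (2.83-fold higher), Sod3 at 1.42 and Gstt1 at 1.19. Adipokines (0.12, percentile 98.7) had Nrg4 at 1.49, against Retn, resistin, at -1.32, but lost their place in 4 of 11 alternative settings, and the sign of the list's median turned in genes well above background on all 3 arrays.

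Ribosomal protein genes stood apart as lower, with a relative median of -0.62 (percentile 0) although 0 of 37 passed 2-fold, and the median shrank to -0.20 with quantile normalization and -0.25 with cyclic loess. Rps18 was at -0.97, Rpl10a at -0.84 and Rps3 at -0.81. Scaled on the spike-in probes, the list's own median moved from -0.67 to -0.003. Branched-chain amino acid catabolism lay at -0.31 (percentile 1.06), with Bcat2 at -0.79 and Hibch at -0.68, and brown and beige genes at -0.37 (percentile 0.64), with Tbx1 at -0.85 and Cpt1b at -0.66 against Cidea at 0.95. The brown and beige list no longer stood apart in 4 of 11 alternative settings, and both lists' own medians turned to the higher side under spike-in scaling, at 0.31 and 0.25.

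The other lists did not stand apart from day 8 to day 20. Adipocyte identity genes had 2 of 20 higher and 1 lower (relative median -0.31, percentile 33.1), with Pck1 at 1.70 as the largest. Late and early adipogenic regulators (0.17 and 0.07), glucocorticoid and cAMP targets (0.06), lipid droplet genes (-0.10), respiratory chain (-0.46), fatty acid oxidation (-0.19), circadian clock (0.21) and housekeeping genes (-0.21) had 0 members past 2-fold. The own medians of the adipocyte identity (-0.36), lipid droplet, fatty acid oxidation, housekeeping, lipolysis, hypoxia, p53 and heat shock lists were below 0 and turned positive under spike-in scaling, quantile normalization and cyclic loess, that of adipocyte identity to 0.31, 0.10 and 0.07. The respiratory chain list turned under spike-in scaling alone among the 4 scalings, and it stood apart as lower in 3 of 11 alternative settings. Hypoxia targets stood apart as higher in 1 of 11 and macrophage markers as lower in 1 of 10. Lipolysis had 1, Pde3b (2.14-fold higher), hypoxia targets 1, Adm at 1.01, and heat shock genes 1 each way, Hspb8 at 1.33 and Hspb1 at -1.23. The list of p53 targets had 3 of 26 higher (0.01), among them Igfbp3 at 1.76 and Plk2 at 1.36. Of 4 endothelial markers, Flt1 was higher by 1.07, and the 3 epithelial markers stayed under 2-fold.

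**Figure D3:**
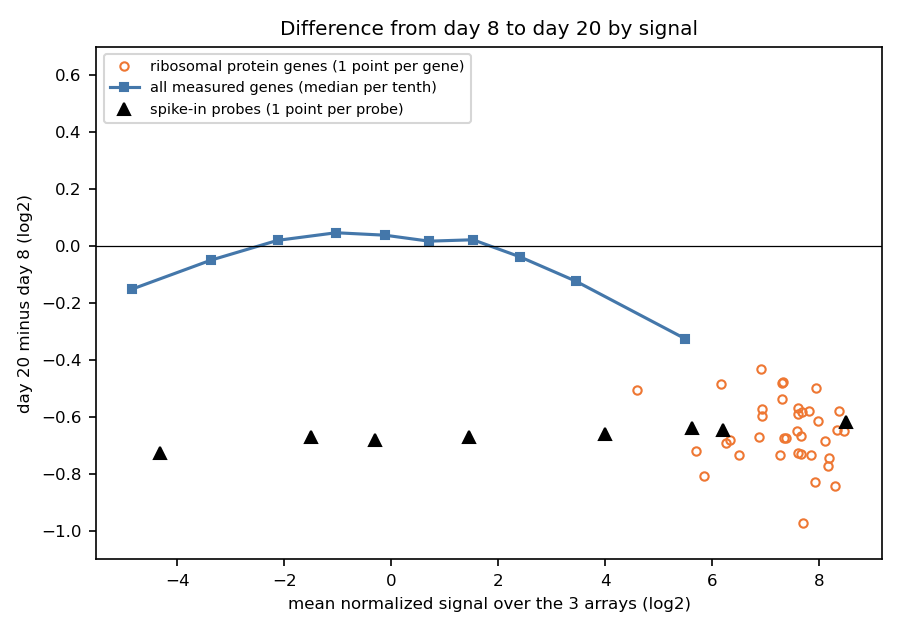
Difference from day 8 to day 20 (log2) against mean normalized signal over the 3 arrays (log2), with squares for the medians of 10 equal bins of all measured genes by signal, circles for ribosomal protein genes and triangles for the 8 spike-in probes well above background. The brightest bin had a median of -0.33 and bin 5 one of 0.04, while the spike-in probes lay between -0.73 and -0.62 at every signal.

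Over the whole course, from day 2 to day 20, Adipoq was 8.65-fold higher (3.11, SD 0.069), Slc2a4 10.8-fold (3.43, SD 0.074) and Pparg 2.94-fold (1.56, SD 0.071), and Cebpb was 2.22-fold lower (-1.15). Dlk1, at 1.01, was past 2-fold only over the whole course and the second step. Lep was at least 2.43-fold higher, Plin1 was at 0.89, Fasn at 0.30, Cebpa at -0.28 and Fabp4 at -0.75. The values of Cebpa and Fabp4 changed sign with cyclic loess, to 0.06 and 0.02, and that of Cebpa with spike-in scaling, to 0.43. Of 1665 genes at least 2-fold higher on day 8 than on day 2, 1424 (85.5%) were at least 2-fold higher on day 20 too, and of 1531 lower genes measured on all days 1306 (85.3%) were lower. Both comparisons share the day 2 array, so any deviation of that array would raise these shares.

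In this comparison 11888 genes were measured, 1840 at least 2-fold higher on day 20 and 2017 lower, with 754 and 446 past 4-fold and bounds for 372 and 197. The share of higher genes was 47.7%, against 65.0% with cyclic loess (2432 higher, 1308 lower) and 85.0% with spike-in scaling (3903 higher, 689 lower). The median of all genes was -0.15, and 0.57 under spike-in scaling. Of 941 genes past 2-fold with another probe, 888 (94.4%) had those probes on the same side. Ghrh (11.61), Adrb3 (9.64), Cfb, complement factor B (9.47), Selenbp1 (8.94), Apol9a, an apolipoprotein L (8.34), and Gstt1 (8.28) were highest, and the bounds were largest for Cox8b (at least 1250-fold higher), Apol9b (at least 940-fold), Mb, myoglobin (at least 629-fold), and Plppr3 (at least 404-fold). Rnase2a (-12.09), Ear1 (-11.74), Ear10 (-10.34), Ear6 (-9.60), the renin gene Ren2 (-8.49) and Lcn2 (-6.65) were lowest, with bounds for Ear2 (at least 9568-fold lower), Retnla (at least 1171-fold), Pip (at least 328-fold) and Krt15 (at least 258-fold).

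Of the 34 lists, 19 stood apart as higher and 2 as lower over the whole course. Interferon response genes had 20 of 24 higher (relative median 3.78), with Psmb9 at 7.40, Gbp3 at 7.34 and Oas1a at 7.01, and chemokines 13 of 24 higher and 4 lower (1.31, and 2.56 in genes above the lower quartile of signal), with Ccl9 at 5.26 and Ccl2 at 5.25. Macrophage markers in the same arrays had 1 of 5 higher, Cd14 at 3.28, and 1 lower, Fcer1g at -1.33 (relative median -0.40, percentile 16.4, again with an own median that turned positive under spike-in scaling). Cell cycle genes had 30 of 31 lower (-3.21), with Tk1 at -4.85, and Ccnd1 at 1.46 as the exception. Muscle markers (1.81, but 0.05 without a filter on dim probes), with Acta1 at 4.22 and Des at 3.50, stood beside actin genes (1.29), with Myl9 at 8.18 and Acta2 at 7.46, matrix proteases (1.44), with Timp3 at 6.66, and preadipocyte genes (1.02), with Pdgfrb at 3.35 and Dcn at 2.59. Lists of adipocyte identity and lipid metabolism were higher again: lipolysis (1.52), cholesterol synthesis (1.24), adipocyte identity (1.23), fatty acid synthesis (1.03) and lipid droplet genes (0.87). Ribosomal protein genes were at -0.68 (percentile 1.95), with 10 of 37 at least 2-fold lower, a place lost in 4 of 11 alternative settings.

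Both steps together sorted 11810 genes measured on all days. Most, 8365, were under 2-fold in both steps, 1488 were higher only in the first and 1426 lower only in the first. In 129 genes both steps were at least 2-fold higher, led by Timp3 (3.43, then 3.22), Aebp1 (3.07, then 3.43), Cfb (6.68, then 2.79), Apol9a (5.85, then 2.50) and Spp1 (3.40, then 2.36). In 48 genes a higher level on day 8 was followed by a lower one, led by Ly6h (6.28, then -1.99), Prcd (3.10, then -1.73), Apoc4 (4.64, then -1.72), Klra2 (3.48, then -1.53) and Fabp12 (1.57, then -1.46). The reverse held in 75 genes, led by Ccl17 (-3.47, then 3.37), Slpi, a secreted protease inhibitor (-3.41, then 2.53), Dpysl3 (-2.07, then 2.38), Bcat1 (-4.06, then 1.96) and the matrix protein gene Dpt (-2.84, then 1.96). In 30 genes both steps were lower, led by Rnase2a (-8.11, then -3.99), Ear1 (-7.94, then -3.80), Klra5 (-3.06, then -2.36), Ear10 (-8.20, then -2.15) and Camp (-2.48, then -2.06). These 4 counts (129, 48, 75 and 30) became 503, 3, 321 and 8 with spike-in scaling, 264, 333, 145 and 74 without a filter on dim probes, and 81, 20, 24 and 15 with normexp. The 2 steps share the day 8 array, so a deviation of that array or culture alone would give genes higher and then lower, or the reverse.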

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

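The 2 tests in this part, and the other scalings of unnamed probes, were chosen only after the results were seen. Signals in data the comparisons do not use came from probes without a gene name and from the spike-in probes.

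Of 12848 unnamed probes with a value on all arrays, 5026 were well above background on both day 2 and day 8. Of these, 422 were at least 2-fold higher on day 8 and 619 lower, 1041 in all, with a median of -0.18. From day 8 to day 20, 408 of 4914 were at least 2-fold apart, 51 higher and 357 lower, with a median of -0.37, and over the whole course 1800 of 4732 were, 385 higher and 1415 lower, with a median of -0.61. With spike-in scaling the surplus turned to the higher side in both, to 289 higher and 19 lower from day 8 to day 20 (median 0.30) and 792 and 424 over the whole course (0.10), while with cyclic loess 88 were higher and 188 lower, and 500 and 843.

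The 8 spike-in probes well above background, whose amount is set by the experimenter, had a median of -0.67 on day 20 relative to day 8 (-0.73 to -0.62) after scaling on the bulk of genes. From day 2 to day 8 they were at -0.05 (-0.07 to 0.09).

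Relative to the bulk of genes, bright genes and ribosomal protein genes were lower on day 20 than on day 8. The brightest bin of genes had a median of -0.33 and ribosomal proteins a relative median of -0.62. Spike-in scaling moved the median of all genes from -0.05 to 0.62. This shift is larger than 0.33, so the brightest bin would then lie on the higher side. The own median of ribosomal proteins was -0.003 under spike-in scaling. Compression of bright signals peculiar to the day 20 array is argued against. The 3 bright spike-in probes lay 0.039 above the 3 of middle signal, with an SD over spike-in probes of 0.033. The gap between the brightest and the middle bin of genes was -0.36. Compression shared by the arrays stays open. The array constants (-9.31 on day 8, -9.86 on day 20) account for most of the spike-in difference. Before scaling the spike-in probes thus had similar intensity on both arrays and could not show shared compression. Whether a signal-dependent trend common to all genes was the cause cannot be decided. After cyclic loess the ribosomal list remained at percentile 0.185 of matched lists, although its relative median shrank to -0.252. All ribosomal genes but Rpl4 (4.59) lay above the mean signal of the brightest bin of genes (5.5), up to 8.46 for Rps14. The matched lists could thus be dimmer, and a remaining trend could give the same percentile. A trend of this kind, as all or part of the cause, stays open. Differences in RNA quality or labelling between the arrays and time in culture also stay open, untested.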

How the results depend on the processing

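The alternatives in this part were chosen before the data were examined, except that normexp had to use median spot signals, which was chosen after the files were seen. No paired analysis was possible because each day has 1 array, and no replicate could be left out for the same reason. The series table and scaling on the median of probes well above background moved 0 of 22 counts and 0 of 102 list medians, and leaving out saturated spots changes nothing because 0 spots were saturated. List medians below are relative to all measured genes, and main values stand in brackets. Of the lists that stood apart in the main values, the cell cycle, late adipogenic, adipocyte identity, lipolysis, hypoxia and interferon lists did so in all 11 alternatives from day 2 to day 8, as did the matrix protease, actin, preadipocyte, cell cycle, interferon and ribosomal lists from day 8 to day 20. Among these 11, the series table and the scalings on the median and on the spike-in probes add 1 constant per array. They could not have changed the place of a list. Signal over background limits what dim genes can show: of the alternatives tried, normexp background correction moved the most counts (14 of 22), and leaving out the filter on dim probes moved 9 of 16. For the shifts below the cause was not tested unless one is given.

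With spike-in scaling, from day 8 to day 20, genes at least 2-fold apart were 2098 higher (441) and 21 lower (214), with bounds for 155 (63) and 9 (65). Over the whole course they were 3903 higher (1840) and 689 lower (2017), with bounds for 86 lower (197). The time course patterns became 503 genes higher in both steps (129), 3 higher then lower (48), 321 lower then higher (75) and 8 lower in both steps (30). These shifts follow from the construction, since 1 constant is added to every gene of an array, which leaves relative list medians as they were. Sign changes among named genes were 28 of 141 from day 8 to day 20 and 7 of 168 over the whole course.

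With cyclic loess, from day 8 to day 20, 127 genes were lower (214) and 20 as bounds (65), and from day 2 to day 20, 1308 (2017) and 127 (197). List medians from day 8 to day 20 were -0.264 for branched-chain amino acid catabolism (-0.311), 0.359 for the unfolded protein response (0.219), 0.331 for lysosome and autophagy (0.249) and -0.252 for ribosomal proteins (-0.622). Over the whole course the ribosomal list was at -0.252 (-0.684), leaving 1 list lower (2). With quantile normalization, from day 8 to day 20, 17 genes were lower as bounds (65), and list medians were 0.301 for fatty acid and triglyceride synthesis (0.147), -0.213 for branched-chain amino acid catabolism, -0.109 for brown and beige genes (-0.366), 0.362 for the unfolded protein response, 0.357 for lysosome and autophagy and -0.199 for ribosomal proteins. Over the whole course the lysosome list was at 1.17 (0.925) and the ribosomal list at -0.263, with 1 list lower (2).

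With normexp, bounds from day 2 to day 8 numbered 119 higher (304) and 38 lower (134), the cell cycle list was at -3.66 (-4.12), and 1 list was lower (2). From day 8 to day 20, 206 genes were higher (441) and 100 lower (214), with bounds for 0 (63) and 5 (65). Medians were 0.42 for the cell cycle (0.623), -0.242 for branched-chain amino acid catabolism, 0.318 for cholesterol synthesis (0.226), 0.958 for matrix proteases (1.18), 0.329 for lysosome and autophagy, 0.078 for immediate early genes (0.292), -0.517 for ribosomal proteins, 0.0802 for muscle markers (0.627) and 0.337 for bone and cartilage markers (1.17). Lep reversed to -0.0406 (1.07). Bounds over the whole course were 148 higher (372) and 61 lower (197), the ribosomal list was at -0.604, and 1 list was lower (2). The time course patterns held 81, 20, 24 and 15 genes, in the order given above. The added offset shrinks differences of dim genes by construction.

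Without a filter on dim probes, which counts differences below background too, 2615 genes were higher from day 2 to day 8 (1665), 694 higher (441) and 1315 lower (214) from day 8 to day 20, and 3212 lower from day 2 to day 20 (2017). The time course patterns held 264, 333, 145 and 74 genes. In the first step, chemokines were at 0.386 (1.28), the interferon list at 3.99 (3.26) and 1 list was lower (2). From day 8 to day 20, branched-chain amino acid catabolism was at -0.233, lysosome and autophagy at 0.327, ribosomal proteins at -0.543, bone and cartilage markers at 0.0174, and muscle markers reversed to -0.00686. Over the whole course, the interferon list was at 4.42 (3.78) and muscle markers at 0.0478 (1.81). With only genes above the lower quartile of signal, which tests fewer genes, 196 were higher (441) and 106 lower (214) from day 8 to day 20, and the patterns held 83, 19, 39 and 18 genes. Chemokines were at 2.33 from day 2 to day 8 and 2.56 from day 2 to day 20 (1.31), with 1 list lower (2) in each. From day 8 to day 20, brown and beige genes were at -0.0617 and immediate early genes at 0.455. In genes well above background on all 3 arrays, brown and beige genes were at -0.114 and adipokines reversed to -0.0609 (0.125), both from day 8 to day 20.

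With the mean of a gene's probes, 1 list was lower from day 2 to day 8 (2), and the ribosomal list was at -0.591 from day 8 to day 20. With the dimmest probe, these were 1 (2) and -0.594, immediate early genes were at 0.131 from day 8 to day 20, hypoxia targets at 2.06 from day 2 to day 20 (1.62), and Rpl22 reversed to 0.734 from day 2 to day 20 (-1.18). The list lost from the lower side from day 2 to day 8 was in each case glucocorticoid and cAMP targets.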

Other observations

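Of the tests below, those of normalization, macrophages and a single Ear transcript were chosen only after the results were seen, as were the gene families and the added lists, while those of interferon genes and eosinophils were set down before their values were seen.

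Genes sharing a symbol stem were compared as families. From day 2 to day 8, subunits of the proteasome were lower as families: Psmc in 6 of 6 cases (median -1.40), Psma in 4 of 7 (-1.12) and Psmd in 6 of 14 (-0.98), with 0 higher. Psmb genes had 1 of 9 lower and a median of -0.65, while Psmb9 was higher by 5.32 and Psmb8 at least 40.1-fold, both immunoproteasome subunits and interferon targets. Psmb10, another subunit of this kind, was at 0.93, and the peptide transporter gene Tap2 at 3.57. Chaperonin genes of the Cct family were lower in 5 of 8 cases (-1.04) and higher in 1, Cct6b at 2.31. The 4 scalings tried kept these medians below 0, the nearest to 0 being -0.46 for Psmb with cyclic loess. Glutathione transferases of the Gstm family were higher in 5 of 5 cases (3.80), with 2.08 as the lowest median in the alternatives, from the mean over probes.

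Small nucleolar RNA host genes (Snhg) were lower in both steps, with medians of -1.39 and -0.91, and 7 of 7 were at least 2-fold lower over the whole course (-2.44). Under spike-in scaling the median of the second step was -0.25. Lectin-like receptor genes of the Klra family were lower from day 8 to day 20 in 7 of 9 cases (-1.53), a median of -0.87 under spike-in scaling and -1.13 with normexp. In the first step they were at -0.76, and at -0.06 without a filter on dim probes. Members of this family are similar in sequence, and which were transcribed is not resolved here. Apol genes were higher from day 8 to day 20 in 3 of 6 cases (1.41), with medians of 0.44 under normexp and 0.34 without a filter on dim probes. In all, 24 of 360 families lay above and 28 below the limits used for lists from day 2 to day 8, and 34 and 25 of 365 from day 8 to day 20.

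Interferon response genes were higher on day 8 than on day 2 by a relative median of 3.26, and so were targets outside the fixed list, with 19 of 23 at least 2-fold higher, 1 lower and a relative median of 2.70. The background correction or a signal-dependent normalization is argued against, since the lowest relative median over normexp, quantile normalization and cyclic loess was 2.73. Immune cells of the macrophage kind are argued against, since 1 of 8 abundant macrophage genes, Cd14, was at least 2-fold higher, and Lyz2, Tyrobp, Laptm5 and Ptprc were not well above background on day 8. All 8 were already in fixed lists, so this was not evidence separate from those lists. Transcription of an interferon gene in the cells cannot be told apart from its absence: 0 of 8 interferon genes were at least 2-fold higher and 3 were above background on day 8, which leaves transcripts too dim for the array, or made between the sampled days. Time in culture stays open, untested, and from day 8 to day 20 the added targets were at 0.36.

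Ear family genes and Retnla were lower on day 8 than on day 2, at -7.65 for Ear2 to -9.77 for Retnla. Eosinophils in the day 2 culture are argued against, since only 3 of 12 eosinophil markers were well above background on day 2 and 0 were at least 2-fold lower on day 8. Epx, Prg2 and Prg3 were among those not well above background on day 2 (1 of the 12, Fcer1g, is also in a fixed list). Whether 1 transcript was read by all Ear family probes or several were transcribed cannot be told apart. The test used the first step only. From day 8 to day 20 the differences of Rnase2a, Ear1 and Ear10, given above and measured on both days, spread more widely. Ear2 was not well above background on day 20. In the first step the differences of the 5 probes had an SD of 0.275, 3.37 times their median technical SD of 0.081. However, their order followed the brightness of the probes (rank correlation 0.90), as unequal response of probes to 1 transcript could also give. Time in culture stays open, untested.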
